A study of Mus musculus with 28 samples.

How the data were processed

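Total RNA from frozen heart tissue of 28 mice was labelled with biotin and hybridised to 1-colour arrays of Affymetrix type, 1 array per animal, with 7 animals in each of 4 groups, per the labels' protocols. The deposited values were intensity values on a linear scale, 1 per probe set and array, from 0 to 26183.2. The submitters' processing notes name RMA. The values themselves did not have the form that RMA gives. They were not on a log scale, the sorted values differed between arrays, and the mean over probe sets, with 2% trimmed at each end, was 250.0 on every array. They were therefore treated as globally scaled signals, although log2 values from RMA had been assumed in the design. The version of RMA, the software that made the scaled signals and any batch, hybridisation date, dose or duration of treatment are not given in the sources used here. No aligner or genome build applies to these arrays.

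The table held 45101 probe sets. The 64 control probe sets whose names start with AFFX were left out of the tests, and 45037 were tested. In the probe annotation 34945 of these had 1 gene symbol, 932 had several and 9160 had none, and the probe sets with 1 symbol named 18193 genes. Only probe sets with 1 symbol gave a gene its name, so genes read only by probe sets with several symbols or none were not analysed here. All 28 arrays were mapped to the sample labels. None of the 378 pairs of arrays held identical values.

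Signals were floored at 0.1, the lowest value above 0, and log2 transformed, which affected 3 values at 0. Group means were fitted to all 28 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend, 24 residual degrees of freedom), without covariates or a replicate block. The contrasts were del337TR against control without WY14643, WY14643 against untreated in controls, WY14643 against untreated in del337TR, del337TR against control under WY14643, and the difference of the WY14643 effects, del337TR minus control. Comparisons that use the same group share its chance values. All tests were two-sided. P values were adjusted by Benjamini and Hochberg over the probe sets of each contrast, with a threshold of 0.05. Errors of log2 fold changes are limma's standard errors, and errors of signals are standard deviations.

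The design, the alternatives and 30 gene lists were fixed before the data were examined, with exceptions named where they occur. The lists covered metabolism, thyroid hormone and PPAR target genes, heart function, stress, matrix, sex-linked genes and markers of other cells. They were written from general knowledge and not taken from the study. Their 484 entries named 447 different genes, so some genes stood on more than 1 list. Of the entries 439 were matched to a probe set. Each gene was represented by its probe set with the highest mean over the arrays. Lists were tested with camera of limma at a preset correlation of 0.01, which compares a list with the other genes, and adjusted over the 30 lists. The same test with an estimated correlation and limma's fry, which asks whether the genes of a list move in 1 direction, were run beside it. For each list the members past the threshold over all probe sets and adjusted over the list alone were counted. Genes were named by a rule, which took the 10 largest rises and 10 largest falls past the threshold with 1 symbol, up to 4 members with the smallest p of each list in each comparison, and every probe set of Thra, Thrb and Ppara. Other genes are said to have been chosen after their values were seen. Where a gene had 2 or more probe sets at an unadjusted p under 0.05, these had opposite signs for 29 of 70 genes in the strain comparison without WY14643, 37 of 229 for WY14643 in controls, 30 of 130 for WY14643 in del337TR, 42 of 328 for strain under WY14643 and 27 of 87 for the difference of effects.

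The alternatives set out beforehand were log2 of the value plus 16, only probe sets above the 40th percentile of the mean, eBayes with trend and robust settings, array weights, quantile normalization, centring of each array on its median, only the 2 groups compared, the replicate number as a block, the first principal component of the residuals as a covariate, a fold of at least 1.5, the mean of the probe sets of a gene, and leaving out each array in turn. A sex covariate from Xist and Eif2s3y, an atrial score covariate from Myl4, Myl7 and Sln, leaving out the array least like its group in each group, and quantile normalization and centring for the lists were added after the data were seen. The tests were also run on 100 splits of the samples, the real one among them. The genes and array measures searched for single far arrays were chosen after values had been seen.

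The fit was tested on simulated data with the arrays' own spread, in which 50 probe sets were changed at each of 4 folds. With the changed probe sets drawn from all, for the strain comparison without WY14643 the test recovered 21 of 50 at a fold of 1.5, 20 at 2, 37 at 4 and 48 at 8. It recovered 12, 23, 35 and 45 for WY14643 in controls, 14, 24, 35 and 48 for WY14643 in del337TR, 17, 27, 39 and 42 for strain under WY14643, and 6, 12, 23 and 39 for the difference of effects. With the changed probe sets drawn from those above the 40th percentile of the mean, the test recovered 25, 36, 48 and 50 for strain without WY14643, 14, 38, 49 and 50 for WY14643 in controls, and 22, 34, 50 and 49 for WY14643 in del337TR. It recovered 23, 31, 49 and 50 for strain under WY14643 and 7, 32, 44 and 48 for the difference of effects. None had the wrong sign in either draw. In each simulation the probe sets of all 4 folds and a list of 41 genes were changed together. The cutoff of Benjamini and Hochberg loosens as more probe sets change, so fewer would be recovered where few change. These counts therefore do not give the power of the tests on the real data. Between 5 and 8 unchanged probe sets were called in the simulations drawn from all probe sets, and between 7 and 15 in those drawn above the 40th percentile. A list of 41 genes shifted by 0.2 on the log2 scale passed camera's threshold in each simulation, and 2 unshifted lists passed in the simulation of strain under WY14643 drawn from all probe sets. The simulated probe sets varied independently, while that list, the respiratory chain, had an estimated correlation of 0.793 in the real data. The simulations therefore do not show how often camera calls unshifted lists of correlated genes. The number of arrays limits the precision, and no detection calls were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.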

Results

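Gene expression was measured in the hearts of 28 mice, with total RNA of 1 animal on each array. The animals formed 4 groups of 7, which were untreated controls, controls given WY14643, untreated del337TR animals and del337TR animals given WY14643. WY14643 activates the nuclear receptor PPARalpha, which switches on genes of fatty acid use. The del337TR strain carries a deletion in a thyroid hormone receptor and stands for resistance to thyroid hormone. The labels gave neither a dose nor a duration of treatment. Each array held 45101 probe sets, and the 45037 that were not controls of the array were tested. Median signals ran from 60.1 to 77.8 between arrays, and the highest signal was 26183.2. The number of arrays, 7 a group, limited the precision. Signals of Xist and Eif2s3y, which mark the X and Y chromosomes, split the arrays into 2 female and 5 male among the untreated controls. The split was 4 and 3 among the untreated del337TR animals, 3 and 4 among the treated controls, and 1 and 6 among the treated del337TR animals. Myl4, an atrial myosin light chain, had signals from 106.9 to 14212.5.

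The receptors named by the study were read first. Thrb, the thyroid hormone receptor beta, had 1 probe set, with log2 differences (n = 7 per group) between -0.18 ± 0.15 (SE) for WY14643 in controls and 0.05 ± 0.15 for strain under WY14643, and 0.15 ± 0.22 for the difference of the WY14643 effects. The labels did not say which part of a receptor gene is deleted, so these signals checked no label. Thra, the receptor alpha, had 3 probe sets, none past the threshold. One of them stood at 0.23 ± 0.12 for strain without WY14643. A pair of others stood at -0.44 ± 0.16 and -0.48 ± 0.22 for WY14643 in controls, where the first stood at -0.03 ± 0.12. Ppara, the receptor that WY14643 binds, stood below 0 with WY14643 in del337TR on its 3 probe sets, by -0.47 ± 0.15, -0.49 ± 0.18 and -0.43 ± 0.20. In controls these also stood below 0 with WY14643, by -0.22 ± 0.15, -0.23 ± 0.18 and -0.32 ± 0.20. None of these passed limma's test over all probe sets.

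The comparison of del337TR with control without WY14643 asked which heart transcripts depend on the receptor mutation alone. Slfn3, a schlafen family gene known from lymphocyte growth control, fell by 4.49 on the log2 scale (SE 0.71, limma adjusted p = 0.0456), and was the only probe set of 45037 past the threshold. Its mean signal was 7.50 ± 7.53 (SD, n = 7) in del337TR and 102 ± 44.2 in controls, and all 7 del337TR arrays lay below all 7 controls. Genes of the fetal and hypertrophy list, those that the stressed ventricle re-expresses, lay above the other genes of the array, with 14 of 16 measured members higher and a median of 0.19 (camera adjusted p = 0.0118). Fibroblast markers did so too, with 8 of 9 higher and a median of 0.16 (camera adjusted p = 0.0118). The list of immediate early and heat shock genes had 17 of 21 members higher, a median of 0.14 and a camera adjusted p of 0.0280. The list of the respiratory chain and ATP synthase had 40 of 41 members higher, a median of 0.05 and a camera adjusted p of 0.0280, a direction of camera that turned with quantile normalization. Of 10000 lists matched on brightness 52.9% lay as high as the respiratory chain and 0% as each of the other 3 lists. The genes of these matched lists were drawn 1 by 1 and need not vary together as list members do, so low shares can come out too low. All 4 calls were lost with an estimated correlation (camera adjusted p = 0.647 for fetal and hypertrophy genes, adjusted p = 0.477 for fibroblast markers and adjusted p = 0.921 for the other two with an estimated correlation). No member of these lists passed limma's test over all probe sets or adjusted over the list alone, and 1, 2, 1 and 0 members, in the order given, had an unadjusted p under 0.05. Among the members, Nppb, the B-type natriuretic peptide, stood at 0.55 ± 0.26 (SE, n = 7 per group) and Tnni1, the slow muscle troponin I, at 1.25 ± 0.70. Tcf21 stood at 0.37 ± 0.15, Pdgfra at 0.43 ± 0.22 and Lum, which encodes the matrix protein lumican, at 0.34 ± 0.16. Btg2 stood at 0.48 ± 0.18, and the respiratory chain genes Cyc1 and Ndufa1 at 0.09 ± 0.10 and 0.09 ± 0.09. The thyroid hormone induced genes had 5 of 13 members higher and a median of -0.07 (camera adjusted p = 0.389). The thyroid hormone repressed genes had 6 of 7 higher and a median of 0.05 (camera adjusted p = 0.389), with Myh7, the slow myosin heavy chain, at 0.41 ± 0.38 (0.07 without replicate 7 of the untreated controls). Atrial markers had a median of 0.51 (camera adjusted p = 0.139) in this comparison. With quantile normalization, an alternative for the lists that was chosen after the data were seen, none of the 4 lists passed. The medians were then 0.18 for fetal and hypertrophy genes, 0.15 for fibroblast markers, 0.16 for immediate early and heat shock genes and 0.00 for the respiratory chain, so only the last median was lost with the scaling. The Slfn3 call was lost with the replicate number as a block, and with sex or an atrial score as a covariate, while the fold stayed at -4.49 ± 0.68, -4.50 ± 0.74 and -4.47 ± 0.76. The limma adjusted p over the settings fitted to all 4 groups, and without each array in turn, ran from 3.38e-07 to 0.598. The lowest came with 16 added to each signal, and the highest without the array least like its group in each group. With 1 array left out the Slfn3 call stayed only without replicates 4 or 5 of untreated del337TR or 1, 2 or 4 of treated del337TR. The number of lists was 2 without replicate 2 or 5 of the untreated controls or replicate 5 or 7 of untreated del337TR, and 7 without replicate 3 of the untreated controls. The call of fetal and hypertrophy genes was kept without each of the 28 arrays in turn (highest camera adjusted p = 0.0460). That of fibroblast markers was lost without replicate 1 of the untreated controls or 6 of untreated del337TR (highest camera adjusted p = 0.0937). The respiratory chain call was lost without replicates 2, 5 or 6 of the untreated controls or 2, 5 or 7 of untreated del337TR (highest camera adjusted p = 0.706). The immediate early and heat shock call was lost without replicates 2, 4, 5 or 7 of the untreated controls or 1, 3, 5 or 7 of untreated del337TR (highest camera adjusted p = 0.176).

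**Figure D1:**
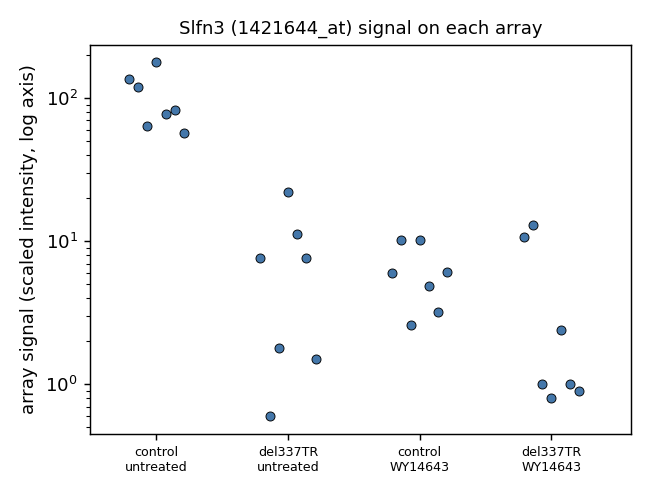
Signal of Slfn3 (scaled intensity, log axis) on each of the 28 arrays, by group, with 1 point per array. The 7 untreated controls lay between 57.1 and 178.6 and the 21 other arrays between 0.6 and 22.

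In this strain comparison 1806 probe sets had an unadjusted p under 0.05 by limma, 748 of them higher and 1058 lower in del337TR, where 2252 are expected by chance. Most of the Slfn3 signals in del337TR lay near the lower end of the arrays' range, so the fold and its standard error depended on how low values were treated. The fold was -4.49 ± 0.71 as reported and -2.31 ± 0.20 (limma adjusted p = 3.38e-07) when 16 was added to each signal.

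The comparison of WY14643 with no treatment in controls asked what this PPARalpha activator does in hearts with intact receptors. There 8 of the 30 lists lay above the other genes of the array. The list of the respiratory chain and ATP synthase had 41 of 41 measured members higher (median 0.16, camera adjusted p = 6.71e-18). The citric acid cycle had 16 of 16 higher (median 0.12, camera adjusted p = 6.68e-07), as had mitochondrial fatty acid beta-oxidation 19 of 19 (median 0.10, camera adjusted p = 3.83e-06). The list of glycolysis, glucose uptake and pyruvate oxidation had 17 of 22 higher (median 0.11, camera adjusted p = 0.000769). The thyroid hormone induced genes had 11 of 13 higher (median 0.20, camera adjusted p = 0.000615). Sarcomere genes had 17 of 21 higher (median 0.14, camera adjusted p = 0.00132, a direction of camera that turned with quantile normalization). Calcium handling genes had 14 of 19 higher (median 0.12, camera adjusted p = 0.00550) and lipogenesis 11 of 14 (median 0.15, camera adjusted p = 0.0190). None of the 8 calls held with an estimated correlation, where camera's adjusted p was 0.325 for beta-oxidation, 0.313 for calcium handling, 0.650 for the sarcomere and adjusted p = 0.319 for the other lists with an estimated correlation. With quantile normalization only the respiratory chain list of these 8 passed, with a median of 0.03 in place of 0.16. The medians of thyroid hormone induced genes, lipogenesis and calcium handling were then 0.13, 0.11 and 0.06, and those of the citric acid cycle, beta-oxidation, glycolysis and the sarcomere 0.02, 0.01, 0.00 and 0.00. Lists that passed only then were the extracellular matrix (median -0.11, 1 of 22 higher) and fetal and hypertrophy genes (median -0.17, 5 of 16 higher), both lower. With arrays centred on their medians these had medians of -0.05 and -0.05 (camera adjusted p = 0.117 and 0.280). The 8 lists that lay above the other genes all stayed past the threshold with this centring, the respiratory chain with a median of 0.22 (camera adjusted p = 5.06e-17). Other genes matched on brightness shifted up as well. Of 10000 lists drawn from them, 77.9% lay as high as beta-oxidation, 14.6% as the sarcomere, 13.2% as the citric acid cycle and 7.02% as glycolysis. It was 0.7% for calcium handling, 0.4% for lipogenesis, 0.02% for the respiratory chain and 0.01% for thyroid hormone induced genes. The drawn genes need not vary together as members of a list do, so low shares can come out too low. The estimated correlation of members was 0.793 for the respiratory chain and 0.201 for thyroid hormone induced genes. The actin 3' to 5' ratio, a measure of RNA quality, was 1.39 ± 0.21 (SD, n = 7) in treated and 1.25 ± 0.12 in untreated controls.

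In the same comparison no probe set passed limma's threshold, 3038 had an unadjusted p under 0.05 (1075 higher and 1963 lower), and the lowest adjusted p was that of Slfn3 (limma adjusted p = 0.187). Slfn3 stood at -4.10 ± 0.71 (SE, n = 7 per group) against the same untreated controls that entered the strain comparison, and it passed when 16 was added to each signal (-2.35 ± 0.20). No list had a member past the threshold over all probe sets or adjusted over the list alone. In limma's test 9 members of the respiratory chain list, 7 of the glycolysis list (5 higher and 2 lower), 5 thyroid hormone induced genes, 3 of lipogenesis, 2 of beta-oxidation, 2 of calcium handling and 1 each of the citric acid cycle and the sarcomere had an unadjusted p under 0.05. Acadvl, which starts the oxidation of very long chain fatty acids, stood at 0.24 ± 0.08, with a mean signal of 8348 ± 786 (SD) against 7081 ± 729. Etfb, which passes electrons from beta-oxidation to the chain, stood at 0.22 ± 0.09, Idh3a of the citric acid cycle at 0.24 ± 0.08, Cyc1 at 0.27 ± 0.10 and Ndufa1 at 0.21 ± 0.09. Pdhb of the pyruvate dehydrogenase complex stood at 0.22 ± 0.09 and Pgk1 at 0.23 ± 0.08. The calcium binding protein gene Hrc stood at 0.30 ± 0.10 and Ryr2, the calcium release channel, at 0.20 ± 0.10. Among thyroid hormone induced genes, Thrsp stood at 0.47 ± 0.22, Hr at 0.61 ± 0.30 and Klf9 at 0.28 ± 0.11. Dgat2, of triglyceride synthesis, stood at 0.51 ± 0.19. Nppa, the atrial natriuretic peptide, stood at -0.70 ± 0.30, Ccn2, connective tissue growth factor, at -0.87 ± 0.39, and Myh7 at -0.64 ± 0.38 (-0.98 without replicate 7 of the untreated controls). The treated controls differed among themselves in these genes. Replicates 1, 4, 6 and 7 had Nppa signals of 2837.7, 4703.4, 4451.9 and 3877, Ccn2 signals of 1604, 1612.9, 1580.5 and 1094.8, and Thrsp signals of 1536.7, 1970.1, 1261.4 and 1769.2. Replicates 2, 3 and 5 had 14345.3, 11891.8 and 14026.9 for Nppa, 5625.4, 5824.3 and 8893.7 for Ccn2, and 695.6, 731.5 and 877.5 for Thrsp. The PPAR target genes of lipid uptake, storage and fuel switching had 15 of 22 members higher, a median of 0.09, a mean of -0.02 and a camera adjusted p of 0.104, a direction of camera that turned with quantile normalization. Among them Angptl4 stood at -0.71 ± 0.46 and Ucp3, the uncoupling protein, at 0.40 ± 0.28. Peroxisomal lipid metabolism had 9 of 16 higher and a median of 0.04 (camera adjusted p = 0.150). Endothelial, fibroblast and leukocyte markers had medians of -0.16, -0.16 and -0.13 (camera adjusted p = 0.289, 0.329 and 0.240). Without replicate 1 of the untreated controls 13 lists passed in place of 8, and lipogenesis lost its call without replicate 3 or 4 of the untreated controls or replicate 1 of the treated controls (highest camera adjusted p = 0.0849).

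**Figure D2:**
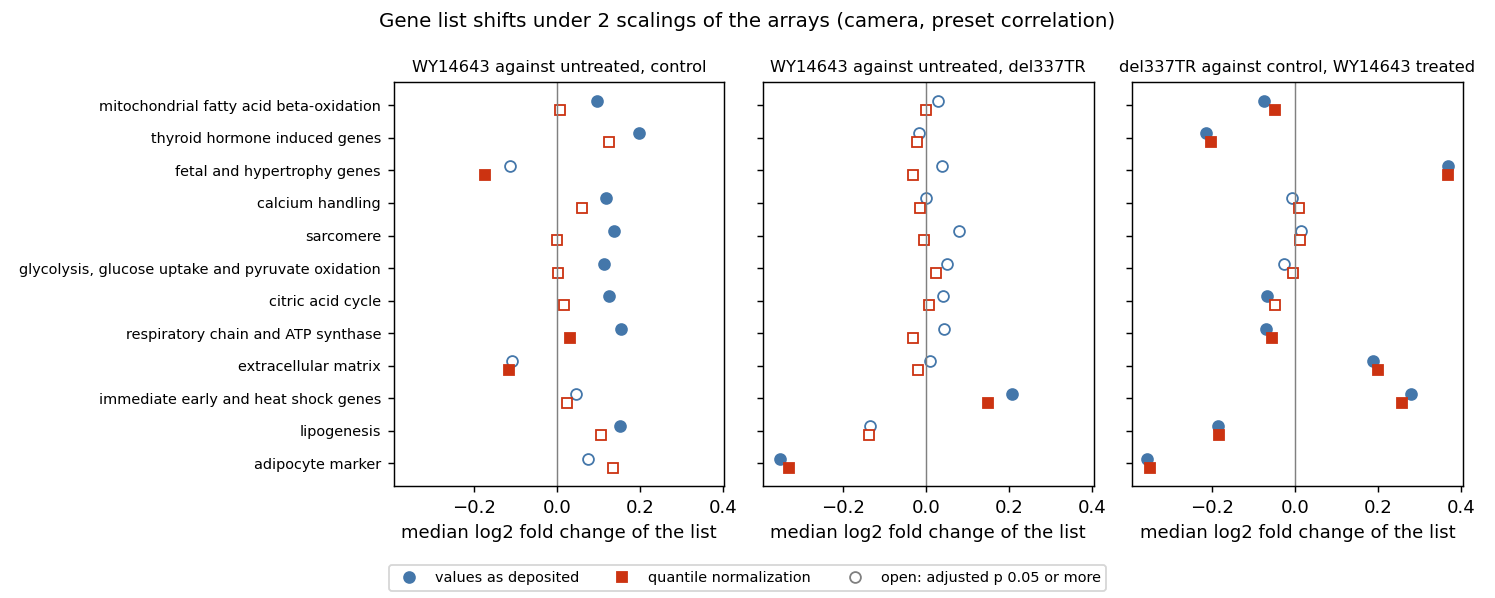
Median log2 fold change of 12 gene lists in 3 comparisons, with circles for the values as deposited, squares after quantile normalization, and filled symbols where camera's adjusted p was under 0.05. In treated controls the respiratory chain median went from 0.16 to 0.03 with quantile normalization, and the sarcomere median from 0.14 to 0.00, while under WY14643 the strain difference of fetal and hypertrophy genes was 0.37 with both.

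The comparison of WY14643 with no treatment in del337TR asked whether the activator acts in the hearts of the mutant strain. Adipocyte markers fell, with 5 of 7 measured members lower and a median of -0.35 (camera adjusted p = 0.00697), a call lost with an estimated correlation (camera adjusted p = 0.214 with an estimated correlation). Over all probe sets no member passed limma's test, and adjusted over the list alone 4 did. These were Cidec, a lipid droplet protein gene (-2.09 ± 0.67, SE, n = 7 per group, limma adjusted p = 0.0144 over the list alone), and the hormone genes Retn (-1.08 ± 0.33, limma adjusted p = 0.0144) and Adipoq (-1.30 ± 0.44, limma adjusted p = 0.0144). The fourth was Lipe, the hormone-sensitive lipase (-0.35 ± 0.14, limma adjusted p = 0.0385). Cidec had a mean signal of 8.60 ± 8.03 (SD) with WY14643 and 26.9 ± 10.5 without, so low that its fold depended on how low values were treated (-0.82 when 16 was added to each signal, still past the threshold over the list alone). Adipoq had 40.5 ± 19.0 and 100.03 ± 54.7. The calls of Cidec, Retn and Adipoq held without each of the 28 arrays left out in turn (highest limma adjusted p = 0.0352). They did not hold without the 4 arrays least like their groups, which were replicate 7 of each group. That of Lipe was lost without replicate 1, 3 or 7 of untreated or any of replicates 2, 4, 5, 6 and 7 of treated del337TR (highest limma adjusted p = 0.117). The list of immediate early and heat shock genes shifted up, with 18 of 21 higher and a median of 0.21 (camera adjusted p = 0.00697, and adjusted p = 0.567 with an estimated correlation). None of its members passed over all probe sets or adjusted over the list alone, and 5 had an unadjusted p under 0.05 by limma (4 higher and 1 lower). Of these the chaperone genes Hspa1a stood at 0.89 ± 0.33, Hspa1b at 0.69 ± 0.29, Dnajb1 at 0.39 ± 0.16 and Hsp90aa1 at 0.25 ± 0.12. Both lists also passed with quantile normalization.

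Among 14 measured members of lipogenesis in this comparison, 12 were lower (median -0.13, camera adjusted p = 0.0569), beside the fall of the adipocyte markers. Over all probe sets no member passed limma's test, and adjusted over the list alone 2 did. These were Fasn, the fatty acid synthase (-0.54 ± 0.16, SE, n = 7 per group, limma adjusted p = 0.0390), and Scd1, a fatty acid desaturase (-0.57 ± 0.19, limma adjusted p = 0.0470, lost with quantile normalization). Both calls were lost with the replicate number as a block and with sex or an atrial score as a covariate. They were also lost without the array least like its group in each group. Untreated del337TR held 4 female arrays and treated del337TR 1. The Fasn call was lost without replicate 1 or 4 of untreated or 3, 5 or 7 of treated del337TR (highest limma adjusted p = 0.136). The Scd1 call stayed only without replicate 1, 2 or 6 of the untreated controls, 3, 5 or 6 of untreated del337TR, 2, 3 or 7 of the treated controls, or 2 or 6 of treated del337TR. Actn1, a cytoskeletal alpha-actinin on the fetal and hypertrophy list, fell by 0.38 (SE 0.10, limma adjusted p = 0.0128 adjusted over the list alone), a call kept without each of the 28 arrays in turn. Of that list 8 of 16 members were higher. Pparg, the adipocyte PPAR, stood at -0.96 ± 0.32. Ehhadh, a peroxisomal PPARalpha target, stood at 0.51 ± 0.27. Of peroxisomal lipid metabolism 8 of 16 members were higher (median 0.01, below 0 with arrays centred on their medians, camera adjusted p = 0.887), and of the PPAR target genes 14 of 22 (median 0.05, camera adjusted p = 0.492). The fibroblast gene Tcf21 stood at -0.45 ± 0.15 and the endothelial gene Vwf at -0.57 ± 0.21. No probe set passed limma's threshold, 2601 had an unadjusted p under 0.05 (1328 higher and 1273 lower), and the lowest limma adjusted p was 0.239 (Cdc16, named after the values were seen). The number of lists past camera's threshold was 2. It became 9 without replicate 2 of untreated del337TR, 6 without replicate 5 or 7 of that group or replicate 1 or 6 of treated del337TR. It was 5 without replicate 5 of treated del337TR, 4 without replicate 1 of untreated or 7 of treated del337TR, and 1 without replicate 6 of untreated del337TR. The call of the heat shock list was lost without that last array and without replicate 5 of treated del337TR (highest camera adjusted p = 0.0810).

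The comparison of del337TR with control under WY14643 asked how the strains differ when WY14643 is given. Thyroid hormone induced genes were lower in del337TR, with 11 of 13 measured members lower and a median of -0.21 (camera adjusted p = 0.000209, and adjusted p = 0.248 with an estimated correlation). Fetal and hypertrophy genes were higher, with 13 of 16 members and a median of 0.37 (camera adjusted p = 0.000426, and adjusted p = 0.334 with an estimated correlation). Thrsp, a thyroid hormone responsive gene of lipid synthesis, had a mean signal of 653 ± 152 (SD, n = 7) in del337TR and 1263 ± 514 in controls. It fell by 0.88 on the log2 scale (SE 0.22, limma adjusted p = 0.00517 adjusted over the list alone), a call kept without each of the 28 arrays in turn. Thrsp read 1536.7, 1970.1, 1261.4 and 1769.2 on replicates 1, 4, 6 and 7 of the treated controls and 695.6, 731.5 and 877.5 on the other 3. Treated del337TR arrays lay between 427.9 and 846.1. Leaving out 1 array at a time does not test how far the difference rests on those 4. Myh7 rose by 1.14 (SE 0.38), Ccn2 by 1.20 (SE 0.39) and Nppa by 0.89 (SE 0.30), each with a limma adjusted p of 0.0349 over the list alone. Xirp1, a repeat protein of the intercalated disc, rose by 0.68 (SE 0.25, limma adjusted p = 0.0466 over the list alone). On the list of thyroid hormone repressed genes 7 of 7 were higher (median 0.13, camera adjusted p = 0.0689). That list passed with quantile normalization, but not with arrays centred on their medians (median 0.05, camera adjusted p = 0.170). Adjusted over that list alone Myh7 also passed (limma adjusted p = 0.0420). Over all probe sets no member of any list passed limma's test, while 6 thyroid hormone induced and 7 fetal and hypertrophy genes had an unadjusted p under 0.05. The hairless gene Hr stood at -0.84 ± 0.30 and the channel genes Kcnd2 and Hcn2 at -0.61 ± 0.26 and -0.50 ± 0.21. Replicates 1, 4, 6 and 7 of the treated controls had Myh7 signals of 6007, 4239.9, 3920.7 and 4519.7, and the other 3 had 17697.1, 18240.4 and 18817.1. The actin 3' to 5' ratio was 1.32, 1.39, 1.43 and 1.82 on the former and 1.19, 1.21 and 1.36 on the latter. The calls of Myh7, Ccn2, Nppa and Xirp1 were lost with sex as a covariate, chosen after the data were seen, and with arrays centred on their medians. Those of Myh7, Ccn2 and Nppa on the fetal list were lost without any of those replicates 1, 4, 6 and 7 and without any of replicates 2 to 7 of treated del337TR (highest limma adjusted p = 0.105). That of Xirp1 stayed only without replicates 3, 5, 6 or 7 of the untreated controls, 4, 5 or 6 of untreated del337TR, 2 or 3 of the treated controls, or 1 of treated del337TR. The call of Myh7 on the thyroid hormone repressed list was lost without replicate 1, 4, 6 or 7 of the treated controls or 2, 3, 4, 6 or 7 of treated del337TR (highest limma adjusted p = 0.133).

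**Figure D3:**
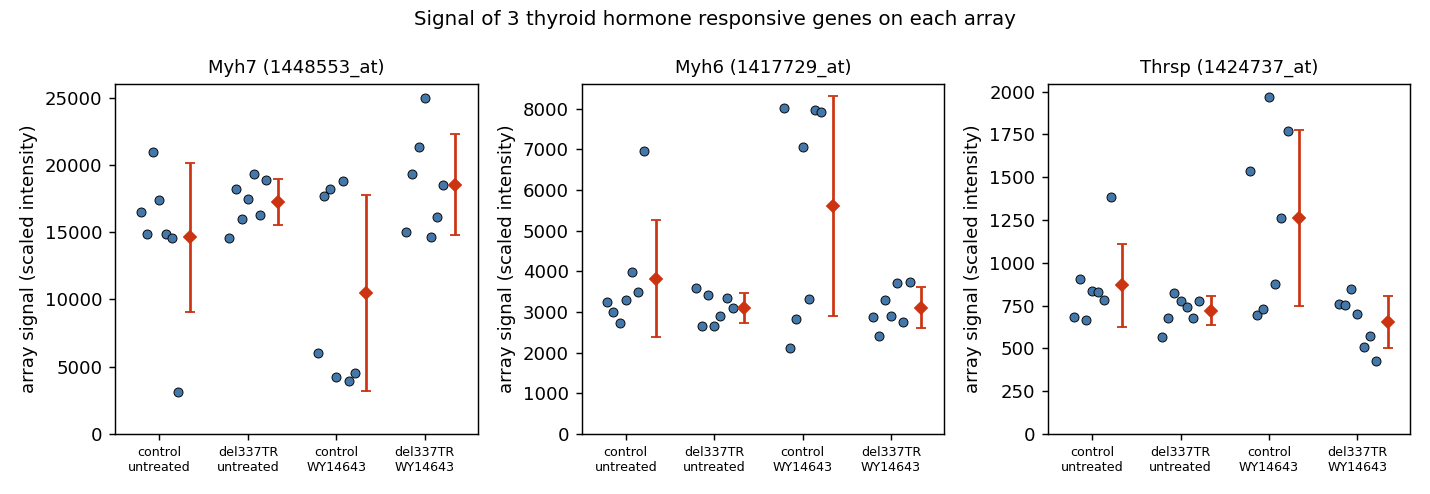
Signals (scaled intensity) of Myh7, Myh6 and Thrsp on each of the 28 arrays, by group, with points for arrays and diamonds with bars for the mean and SD of 7 arrays. Myh7 lay between 3102.7 and 6007 on 5 control arrays, 4 of them treated, and between 14554 and 24980.9 on the 23 others, and the 5 arrays had the highest signals of Thrsp and of the Myh6 probe set shown, but not of the second Myh6 probe set.

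Further lists differed between the strains under WY14643. Lipogenesis was lower in del337TR, with 12 of 14 measured members lower and a median of -0.19 (camera adjusted p = 0.000350, and adjusted p = 0.152 with an estimated correlation). It was the list that passed limma's rotation test fry (adjusted p = 0.0317). Adipocyte markers were lower beside it, with 5 of 7 lower and a median of -0.36 (camera adjusted p = 0.0324, and adjusted p = 0.334 with an estimated correlation), a call lost with arrays centred on their medians. Mitochondrial lists were slightly lower, with 38 of 41 members of the respiratory chain (median -0.07, camera adjusted p = 0.000426), 15 of 19 of fatty acid beta-oxidation (median -0.07, camera adjusted p = 0.00719) and 14 of 16 of the citric acid cycle (median -0.07, camera adjusted p = 0.0412). With an estimated correlation these gave adjusted p = 0.831, 0.755 and 0.755. Of 10000 lists matched on brightness, drawn as before, 0% lay as low as the respiratory chain, 10.1% as beta-oxidation and 1.86% as the citric acid cycle. The extracellular matrix list was higher, with 21 of 22 members and a median of 0.19 (camera adjusted p = 0.000426, and adjusted p = 0.583 with an estimated correlation). So was the list of immediate early and heat shock genes, with 19 of 21 and a median of 0.28 (camera adjusted p = 0.000537, and adjusted p = 0.408 with an estimated correlation). Adjusted over the list alone, 1 member of lipogenesis (Thrsp) and 0 members of the other 6 lists just named passed limma's test. Thrsp is also on the list of thyroid hormone induced genes, so these lists are not separate. Its high signals in the treated controls were those of replicates 1, 4, 6 and 7. An unadjusted p under 0.05 was found for 4 members of lipogenesis, 4 adipocyte markers, 2 of the respiratory chain, 2 of beta-oxidation, 0 of the citric acid cycle, 1 of the matrix and 6 heat shock and immediate early genes (5 higher and 1 lower). Cpt2, of carnitine-dependent fatty acid entry into mitochondria, stood at -0.34 ± 0.12 (SE, n = 7 per group), Acadvl at -0.19 ± 0.08, Cox7a1 at -0.23 ± 0.11, Tgfb2 at 0.90 ± 0.29 and Hsp90aa1 at 0.34 ± 0.12. With quantile normalization all of these directions stayed, and the citric acid cycle no longer passed. Without replicate 7 of the treated controls 5 lists passed in place of 9, and the calls of the matrix, respiratory chain, citric acid cycle and adipocyte lists were among those lost (highest camera adjusted p of the matrix list = 0.0559).

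The remaining calls under WY14643 that depended on single arrays were those of the respiratory chain (lost without replicate 1 of treated del337TR, highest camera adjusted p = 0.0771) and beta-oxidation (without replicate 1 or 7 of treated del337TR, 0.0856). The others were those of the adipocyte markers (lost without replicate 2 of the treated controls or 7 of treated del337TR, highest camera adjusted p = 0.104) and the citric acid cycle (without replicate 1, 3, 4 or 6 of the treated controls or 1, 5 or 7 of treated del337TR, 0.267). Nuclear receptors and coregulators did not shift as a list (12 of 20 higher, median 0.05, below 0 with arrays centred on their medians, mean -0.06, camera adjusted p = 0.80), but 2 members passed limma's test adjusted over the list alone. Ppard, the PPAR found in most tissues, fell by 0.67 (SE 0.18, n = 7 per group, limma adjusted p = 0.0151), with mean signals of 150 ± 22.9 (SD) in del337TR and 242 ± 65.0 in controls. This was lost without replicate 1 of treated del337TR (limma adjusted p = 0.0548). Pparg fell by 1.11 (SE 0.32, limma adjusted p = 0.0185), lost without replicate 4 of the treated controls or 1, 5 or 7 of treated del337TR (highest limma adjusted p = 0.0655). Smtn, a smooth muscle marker, rose by 0.32 (SE 0.11, limma adjusted p = 0.0373 over its list alone), lost without replicate 1, 5 or 7 of the treated controls or 1, 3, 5, 6 or 7 of treated del337TR (highest limma adjusted p = 0.126). Of the 6 markers of that list 4 were lower. The PPAR targets Ucp3 and Plin4, a lipid droplet coat gene, stood at -0.87 ± 0.28 and -0.45 ± 0.16. Atrial markers had a median of 0.79 (6 of 8 higher, camera adjusted p = 0.453) and fibroblast markers a median of 0.11 (9 of 9 higher, camera adjusted p = 0.0695, past the threshold with quantile normalization). With arrays centred on their medians the fibroblast markers had a median of 0.03 (camera adjusted p = 0.170). No probe set passed limma's threshold, 3991 had an unadjusted p under 0.05 (2363 higher and 1628 lower), and the lowest limma adjusted p was 0.403 (Rmc1, named after the values were seen).

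The difference of the WY14643 effects, del337TR minus control, asked whether the mutation changes the response to WY14643. The effects on 6 of the 30 lists were lower in del337TR. Other lists of energy and lipid metabolism did not pass, with a camera adjusted p of 0.454 for glycolysis and for peroxisomal lipid metabolism, 0.603 for the PPAR target genes (10 of 22 higher), 0.791 for ketone bodies and 0.807 for cholesterol synthesis. The respiratory chain list was lower for 39 of 41 measured members (median -0.12, camera adjusted p = 3.87e-06), and lipogenesis for 12 of 14 (median -0.22, camera adjusted p = 0.000862). Beta-oxidation was lower for 17 of 19 (median -0.08, camera adjusted p = 0.0181), and the citric acid cycle for 14 of 16 (median -0.10, camera adjusted p = 0.0181). Thyroid hormone induced genes were lower for 12 of 13 (median -0.15, camera adjusted p = 0.0181) and adipocyte markers for 5 of 7 (median -0.22, camera adjusted p = 0.0223, a call lost with arrays centred on their medians). Of 10000 lists matched on brightness 59.2% lay as low as beta-oxidation and 15.1% as the citric acid cycle, against 0.5% for adipocyte markers, 0.09% for thyroid hormone induced genes, 0.01% for the respiratory chain and 0% for lipogenesis. These shares again do not allow for members that vary together. None of the 6 calls held with an estimated correlation, with adjusted p = 0.217 for lipogenesis, 0.454 for adipocyte markers, 0.612 for thyroid hormone induced genes and 0.875 for the other 3. Over all probe sets no member passed limma's test, and adjusted over the list alone 2 adipocyte markers did, with Adipoq at -1.87 ± 0.62 (SE, n = 7 per group, limma adjusted p = 0.0371) and Retn at -1.22 ± 0.46 (limma adjusted p = 0.0480). Unadjusted p under 0.05 was reached by 3 adipocyte markers, 3 thyroid hormone induced genes (1 higher and 2 lower), 2 of lipogenesis and 0 of the other 3 lists. Scd1 stood at -0.85 ± 0.28, Thrsp at -0.64 ± 0.31, Klf9 at -0.35 ± 0.15, Pparg at -1.25 ± 0.45 and Ppard at -0.68 ± 0.25. Acadvl stood at -0.21 ± 0.12, Cyc1 at -0.25 ± 0.14 and Ndufa1 at -0.24 ± 0.13. The potassium channel gene Kcnj2 stood at 2.36 ± 0.83. Slfn3 passed only when 16 was added to each signal (2.15 ± 0.29). No probe set passed limma's threshold, 2207 had an unadjusted p under 0.05 (1466 higher and 741 lower), and the lowest limma adjusted p was 0.439 (St8sia2, named after the values were seen). With quantile normalization all 6 directions stayed, and beta-oxidation, the citric acid cycle and thyroid hormone induced genes no longer passed. Their medians were then -0.01, -0.04 and -0.18, so that of the thyroid hormone induced genes did not shrink. The extracellular matrix list then passed, with 19 of 22 members higher (median 0.12, and 0.10 as deposited with a camera adjusted p of 0.141). With arrays centred on their medians its median was 0.01 (camera adjusted p = 0.251). The calls of the respiratory chain and lipogenesis were kept without each of the 28 arrays in turn. The treated controls in this difference include replicates 1, 4, 6 and 7, which had low Myh7. Their group had an actin 3' to 5' ratio of 1.39 ± 0.21 (SD, n = 7). It was 1.25 ± 0.12 in untreated controls, 1.29 ± 0.08 in untreated and 1.23 ± 0.09 in treated del337TR. The number of lists became 2 without replicate 7 of the treated controls or of treated del337TR, and 3 without replicate 2 or 6 of the untreated controls, replicate 5 of untreated del337TR or replicate 1 of treated del337TR.

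Single arrays also ended calls in the test of that difference. Beta-oxidation lost its call without any of the 6 arrays that lowered the number of lists to 2 or 3 or replicate 7 of untreated del337TR (highest camera adjusted p = 0.166), and the citric acid cycle without any of the same 6 (0.166). Thyroid hormone induced genes lost it without any of the 6, replicate 3 of untreated del337TR or replicate 1 or 6 of the treated controls (highest camera adjusted p = 0.0836). Adipocyte markers lost it without replicate 7 of the untreated controls, 4 or 7 of untreated del337TR, 2 or 7 of the treated controls or 7 of treated del337TR (highest camera adjusted p = 0.0999). Adipoq kept its limma call over the list alone without 18 of the 28 arrays. It lost it without replicate 1, 3 or 5 of the untreated controls, 1, 4 or 6 of untreated del337TR, 4 or 7 of the treated controls, or 6 or 7 of treated del337TR (highest limma adjusted p = 0.0688). With sex as a covariate, chosen after the data were seen, both Adipoq and Retn lost it. Retn kept it only without replicate 4 or 6 of the untreated controls, 2, 3 or 5 of untreated del337TR, 1, 2 or 3 of the treated controls, or 1, 3 or 5 of treated del337TR (highest limma adjusted p = 0.0949).

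Across all probe sets the WY14643 effects in the strains, which share no arrays, had a Pearson correlation of 0.070 and a Spearman correlation of 0.0765, and 52.8% of probe sets had the same sign. The strain effects without and with WY14643, which also share no arrays, had correlations of 0.0482 and 0.0655, with 53.0% of the same sign. With only probe sets above the 40th percentile the Pearson correlations were 0.111 and 0.0990, and that of the strain effects was 0.0104 with sex and 0.0906 with an atrial score as a covariate, both chosen after the data were seen. These are correlations across genes, and genes are not independent replicates.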

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

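Tests of the Myh7 arrays, of Slfn3, of the share of heart muscle and of single far arrays were chosen only after the result was seen. For 18 measures in each of the 4 groups, 72 sets of 7 values, 17 values on 9 arrays lay far from the others of their set. Chance gives about 1 in 20 sets, or 3.6, and the genes tried were chosen with their values known. Replicate 7 of the untreated controls had a Myh7 signal of 3102.7 (nearest other array 14554), a Myh6 signal of 6949.1 (3971.9) and a Thrsp signal of 1383.6 (902.9). Replicate 3 of that group had a Ppara signal of 694 (1104.1). Retn was 231.6 on replicate 7 of untreated del337TR (156) and 154.3 on replicate 1 of treated del337TR (84.6). Adipoq was 215 on replicate 4 of untreated del337TR (103.3) and 152 on replicate 7 of the treated controls (81.2). Scd1 was 1560.0 on replicate 4 of untreated del337TR (1013.6), and Acadvl was 10004 on replicate 7 of the treated controls (8520.9). The mean correlation with the own group was 0.911 on replicate 7 of untreated del337TR (0.922) and 0.904 on replicate 7 of the treated controls (0.923). The actin 3' to 5' ratio was 1.52 on replicate 7 of the untreated controls (1.26) and 1.82 on replicate 7 of the treated controls (1.43), the highest of their groups. The 18S control signal was 1623.5 on replicate 5 of the untreated controls (5869.8), 1230.7 on replicate 1 of untreated del337TR (7474.3) and 12483.1 on replicate 5 of the treated controls (9284.8). The WY14643 effect differed between the strains for 6 lists, tested as a difference. Their camera adjusted p was 3.87e-06 for the respiratory chain, 0.000862 for lipogenesis, 0.0181 each for beta-oxidation, thyroid hormone induced genes and the citric acid cycle, and 0.0223 for adipocyte markers. None of the 6 calls held with an estimated correlation (camera adjusted p from 0.217 to 0.875).

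Other splits of the samples, 100 with the real one, bear on each comparison. For strain without WY14643 chance was not excluded for the called probe sets (real value 1, highest other split 2, 8 splits as large), those at an unadjusted p under 0.05 (1806, 2999, 61 splits) or the lists (4, 14, 55 splits). For WY14643 in controls it was not excluded for the unadjusted count (3038, 4030, 7 splits) or the lists (8, 11, 14 splits). For WY14643 in del337TR it was not excluded for the unadjusted count (2601, 3345, 14 splits) or the lists (2, 13, 79 splits). For strain under WY14643 few splits reached the unadjusted count (3991, 4252, 2 splits), and chance was not excluded for the lists (9, 14, 13 splits). No other count was reached as rarely, and the counts were not corrected for their number, so that 1 count does not exclude chance. For the difference of the effects it was not excluded for the unadjusted count (2207, 3605, 33 splits) or the lists (6, 13, 29 splits). In these last 4 comparisons limma called 0 probe sets, which all 100 splits reach whatever they hold, so the splits decide nothing there (highest other split 1, 2, 2 and 1). The list calls of camera at its preset correlation, those for the difference included, were therefore no more numerous than grouping by chance can give.

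The respiratory chain list shifted up with WY14643 in controls by a median of 0.16, and 41 of 41 members were higher. Quantile normalization left a median of 0.0319, with 33 of 41 higher and the list still past camera's threshold. It gives all arrays the same sorted values, so it can take out a real shift of bright genes along with one from array scaling. Centring, which moves all probe sets of an array alike, left a median of 0.217 (camera adjusted p = 5.06e-17). How much came from array scaling that leaves bright probe sets shifted therefore cannot be told. Genes matched on brightness had a median of 0.126, just above the 0.8 of the list's median asked for, although 0.02% of 10000 matched lists reached the list's own. That share does not allow for members that vary together. A higher share of heart muscle cells cannot be told apart, since 4 of 7 marker lists of other cells had a median below 0 and their shifts differed by at most 1.25 standard errors. An effect of WY14643 stays open.

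Myh7 was low and Myh6 high on replicate 7 of the untreated controls and replicates 1, 4, 6 and 7 of the treated controls, with Myh6 (named after its values were seen) at 6949.1, 8017.4, 7046.9, 7962.1 and 7925.9 on 1 of its probe sets, while the second read 15741 to 19894.5 there and up to 20931.5 on the others. Whether samples were swapped between the strains cannot be told from Myh7. The 5 arrays were picked as those below the widest gap of its signals, and all were controls. That 0 of 14 del337TR arrays had Myh7 as low follows from this pick. Atrial tissue as a cause shared by the 5 is argued against by Myl4, a single atrial gene. It read 9488.6, 435.8, 1761.7, 1875.6 and 1467.9 on the 5 in the order named, with a median of 4542.2 on the other 23. That 17 of these 23 lay inside the range of the 5 adds little, since that range is wide. RNA degradation cannot be told apart, since the actin 3' to 5' ratio lay above all 23 others on 4 of the 5 (1.52, 1.32, 1.39, 1.43 and 1.82 in the order given), but the Gapdh ratio did so on 0. Single wrongly labelled samples cannot be told apart, since it is not known whether the Thrb probe set (log2 difference between untreated strains -0.0968) reads the deletion, and a difference in thyroid hormone action between animals, by strain or treatment, stays open and untested.

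Slfn3 was low in untreated del337TR and also in both treated groups, so its call rested on high signals in the untreated controls. A hybridisation batch that shifts these arrays in general cannot be told apart. Between the untreated strains 1806 probe sets had an unadjusted p under 0.05, where chance gives 2252 and 61 of 100 splits gave as many. That count shows no general shift between these groups, but a spread left out of the fit can lower it. Between treated and untreated controls the count was 3038, which 7 of 100 splits reached. Besides Slfn3, 1 probe set (Gskip, named after its values were seen) set the untreated controls apart from all 21 other arrays, and 1 did so for the treated controls, where chance gives 0.0761 per group. The signal of the Slfn3 probe set alone cannot be told apart, since the probe set shared by Slfn3 and Slfn4 stood at -0.353 (SE 0.30) at signals of 2 to 9.9. An effect of strain and treatment stays open.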

How the results depend on the processing

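Tests with quantile normalization or centring for the lists, with sex or an atrial score as a covariate and without the array least like its group were chosen only after the result was seen. The 1 probe set called for strain without WY14643 (Slfn3) became 0 with only probe sets above the 40th percentile, which leaves out Slfn3 itself, and with the replicate block, the first residual component, the sex covariate, the atrial score covariate and without the array least like its group. It also became 0 with only the 2 groups compared, where fewer arrays enter. The 0 probe sets called by limma for WY14643 in controls (3038 at an unadjusted p under 0.05) became 1 with 16 added to the values (Slfn3) and 3 with only the 2 groups compared. These 3 were Slfn3, Fry and a probe set without a gene symbol, named after their values were seen. The 0 called by limma for the difference of effects (2207 at an unadjusted p under 0.05) became 1 with 16 added (Slfn3). Leaving out 1 array gave 0 to 1 called probe sets for strain without WY14643, 0 to 1 for WY14643 in controls (1 without replicate 6 of untreated del337TR), 0 to 1 for WY14643 in del337TR (1 without replicate 3 of the untreated controls) and 0 to 0 by limma for the other comparisons (3991 and 2207 at an unadjusted p under 0.05). The number of lists past the threshold was 4, 8, 2, 9 and 6 in the order of the report. With an estimated correlation it became 0 in every comparison, and with fry 0, 0, 0, 1 and 0. With quantile normalization it became 0 for strain without WY14643 and 3 for WY14643 in controls. It became 6 for WY14643 in del337TR with only probe sets above the 40th percentile, 7 there and 2 for the difference with the sex covariate, and 1 for the difference with the gene mean of probe sets. Without the array least like its group it became 0, 7, 4 and 3 in all comparisons but WY14643 in controls. Leaving out 1 array gave 2 to 7, 7 to 13, 1 to 9, 5 to 11 and 2 to 7 lists. With quantile normalization camera's direction turned for the respiratory chain list in strain without WY14643 (camera adjusted p = 0.561) and the sarcomere list with WY14643 in controls (camera adjusted p = 0.671). Of the 29 list calls quantile normalization kept 14 and ended 15, these 2 among them. The calls kept were 29 with 16 added, 28 with the filter, 27 with centring, 27 with the replicate block, 26 with the atrial score, 22 with the sex covariate, 17 with gene means, 17 without the least alike arrays, 1 with fry and 0 with an estimated correlation. The correlation of the strain effects went from 0.0482 to 0.0990 with only probe sets above the 40th percentile, 0.0104 with the sex covariate and 0.0906 with the atrial score covariate. That of the WY14643 effects moved by less than its jackknife error of 0.0428 in each alternative tried. Where no construction is named, the cause was not tested. Of 42 same-numbered pairs of arrays 5 had a correlation of deviations above 0.1 (range -0.122 to 0.190), and 11 matched their own number best. The mean correlation was 0.0329 for the same number and -0.00535 for different numbers. The array least like its group was replicate 7 in every group. Something shared by arrays of the same number is therefore not excluded. Besides the Slfn3 call, the replicate block changed no count of probe sets or lists by over 1.5 times. Low signal over background limited the size of the Slfn3 fold, which was -4.49 as reported and -2.31 with 16 added.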

Other observations

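The comparison of the probe sets of Myh6 was among the tests chosen only after the result was seen. Lists not described above stayed short of camera's threshold in every comparison. Blood cell markers had 4 of 5 members higher with WY14643 in del337TR (median 0.31, camera adjusted p = 0.0569), and nerve and Schwann cell markers 5 of 6 (median 0.29, camera adjusted p = 0.0569). Ketone body genes had 3 of 4 members higher with WY14643 in controls (median 0.14, camera adjusted p = 0.0597), with Oxct1 at 0.20 ± 0.08 (SE, n = 7 per group). Antioxidant and metal response genes had 13 of 18 higher there (median 0.10, camera adjusted p = 0.0768). The sex-linked genes had a median of -1.32 for strain without WY14643 (camera adjusted p = 0.0719), beside the unequal sexes of these groups. The lowest camera adjusted p over the comparisons was 0.519 for ion channels and gap junctions, 0.783 for the circadian clock, 0.394 for cholesterol synthesis and 0.726 for skeletal muscle markers. The potassium channel gene Kcnj2 stood at -1.57 ± 0.58 and the calstabin gene Fkbp1b at 1.67 ± 0.55 for strain without WY14643, and neither passed limma's test. The second probe set of Myh6 stood at 0.22 with WY14643 in controls, where the first stood at 0.44.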
